A study of Drosophila melanogaster with 3 samples.

How the data were processed

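Chromatin immunoprecipitation followed by sequencing was done with an antibody to GFP on 3 biological replicates of whole embryos, aged 4 to 24 hours and of both sexes, from a transgenic fly line with GFP at the C-terminus of abd-A. Chromatin was sheared by sonication to fragments of 200 to 800 bp, per the labels' protocols. The labels give 1 group and a replicate number for each sample. The embryo age was read from the sample source, since the age field holds a number that looks like a converted date.

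The authors deposited 5 peak lists in narrowPeak format on the dm6 assembly: 1 per replicate, 1 called on the alignments of all 3 replicates together (the pooled list) and 1 thresholded by the irreproducible discovery rate (IDR) from the replicate lists and the pooled list, per the text records deposited with the files. Each replicate list was called against the same control file, per those records. The aligner, the peak caller and the IDR threshold are not given in the sources used here, and no control library was analysed here. The signal value of each peak in the deposited files was treated as a score of the authors' peak caller, and was used only to rank peaks within a list or relative to that list's median. The −log10 q-value in the deposited files reached a ceiling in 93.8% of IDR peaks, so it was not used for ranking. The deposited p-value column was empty in the sense of the format, with a placeholder in each row.

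The IDR list was the 8143 strongest of the 30000 pooled peaks by signal value, and 517 of its entries repeated an interval with another summit. Each summit was counted as a peak. Replicate and pooled lists each ended at 30000 peaks, so their length carries no information about depth, and the number of reads behind each list was unknown. Peaks were tested against chromosome lengths, and none passed a chromosome end.

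Genes came from Ensembl release 115 (FlyBase release 6.54) on genome release 6, which shares its coordinates with dm6. Analysis was limited to the 6 main arms, with 18164 genes, of which 13945 code for protein, and 194 genes on other sequences were left out. In the lists 3 symbols were matched to renamed genes. Analysis was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

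Tests, gene lists and words were fixed before the data were examined. Replicates were compared by the share of the 8143 strongest peaks overlapped by at least 1 bp, with 100 rotations of 1 list along each chromosome as chance. Summits were assigned to classes in the order promoter (500 bp around a transcript start), 5' UTR, 3' UTR, coding exon, other exon, intron and intergenic, and compared with 1000 rotations. A summit within 500 bp of a start therefore counted as promoter even in a coding exon, and separate densities by distance to coding sequence had no such order. Gene lists were tested by the number of genes with a summit in the gene body extended by 2000 bp, against 10000 random lists of the same gene class matched on length in 20 bins. The median number of peaks per gene of each list was also given as a percentile of those random lists, without a p-value. Where a bin held fewer other genes than list members, genes were drawn with replacement, so a random list could hold a gene repeatedly. Sequence words were sought on both strands in 101 bp around each summit and around a position 500 bp away on a random side, with an exact McNemar test. Strong and weak peaks were compared by Fisher's exact test between the strongest and weakest 20% of the list. All tests were two-sided, with Benjamini-Hochberg adjustment within each family. Intervals are 95% Clopper-Pearson intervals and cover counting error only.

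These p-values refer to positions in 1 genome, not to samples, and no p-value compares conditions. The smallest p possible was 0.000200 for lists and 0.00200 for rotations. Peaks, genes and list members are not independent, and several lists share members.

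The genes named were chosen by a rule fixed beforehand: the nearest protein-coding start of each of the 20 strongest IDR peaks, every Hox gene and every gene described as regulated by abd-A or Ubx, the 3 genes with the most IDR peaks of each other list, and the 10 coding genes with the most IDR peaks. Noncoding RNA genes over a summit and the window on 3L were named after the values were seen.

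On simulated data the list test called 0 of 40 unchanged lists and 9 of 10 changed ones over 18164 genes. The overlap measure gave 62.1% where 62.2% was built in, over 8143 peaks. The word test gave a planted difference of 9.54 percentage points for 9.64 over 5000 random sequences. It called 5 of 200 pairs of random yes-or-no values over 5000 simulated peaks. These had no difference in base composition between centre and flank, unlike the summits, so the check does not cover that difference. The location test called 3 of 70 classes of randomly placed peaks.

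Alternatives were other overlap rules (50% of both peaks, or summits within 100 bp), 1000 or 5000 strongest peaks, the stronger 50% of the IDR list, promoters of 250 or 1000 bp, a gene window of 1000 bp around starts or of 10000 bp around the body, lists not matched on length, word windows of 100 bp on each side, flanks at 1000 bp, other strength bins, and leaving out each replicate. Alternatives added after seeing the data were the weaker pooled peaks as background, all 30000 pooled peaks for the chromosome densities, and random lists matched on the sequence lying over 300 bp from coding exons.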

Results

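The data described where peaks were called for a GFP-tagged form of abd-A in the genome of Drosophila melanogaster embryos. A region or gene is called bound where it holds a peak, and nonspecific precipitation was not separated from binding. abd-A is a Hox gene of the Bithorax complex, and its homeodomain protein specifies the identity of abdominal segments. Chromatin was taken from whole embryos of both sexes, aged 4 to 24 hours, of a line carrying abd-A with GFP at the C-terminus, and was precipitated with an antibody to GFP. The series held 1 group of 3 biological replicates and no second condition, so the comparisons were between replicates and between bound regions and the rest of the genome. Each replicate list and the pooled list held 30000 peaks, and the list kept after thresholding by the irreproducible discovery rate (IDR), which measures how well peak ranks repeat, held 8143. The IDR peaks covered 3.06 Mb, or 2.29% of the main chromosome arms, with a median width of 476 bp. Read depth was unknown from the peak lists, so equal numbers of the strongest peaks were compared between replicates.

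The first question was whether the replicates marked the same regions. The 2 strongest sites of the pooled list, in the bxd region of the Bithorax complex and near Rh5, ranked among the 3 strongest peaks of each replicate. Among the 8143 strongest peaks per replicate, 81.1% ± 1.22 (SD, 3 pairs) were overlapped by the other replicate, against 4.62% for rotated lists and at most 6.53% in any rotation. Replicates 1 and 3 shared 82.5%, replicates 1 and 2 shared 80.3% and replicates 2 and 3 shared 80.4%. IDR peaks were found among the 8143 strongest peaks in 88.4% ± 1.41 of cases (SD, n = 3), 5928 of them (72.8%) in all 3 replicates and 21 in none. Across IDR peaks, which are not independent replicates and were selected by pooled signal, Spearman's rho of peak strength was 0.648 for replicates 1 and 2, 0.757 for 1 and 3, and 0.674 for 2 and 3. The 3 lists were called against the same control file, and their overlap can include positions set by that control. The IDR list was made from these same replicates, so its support in them is not independent evidence.

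**Figure D1:**
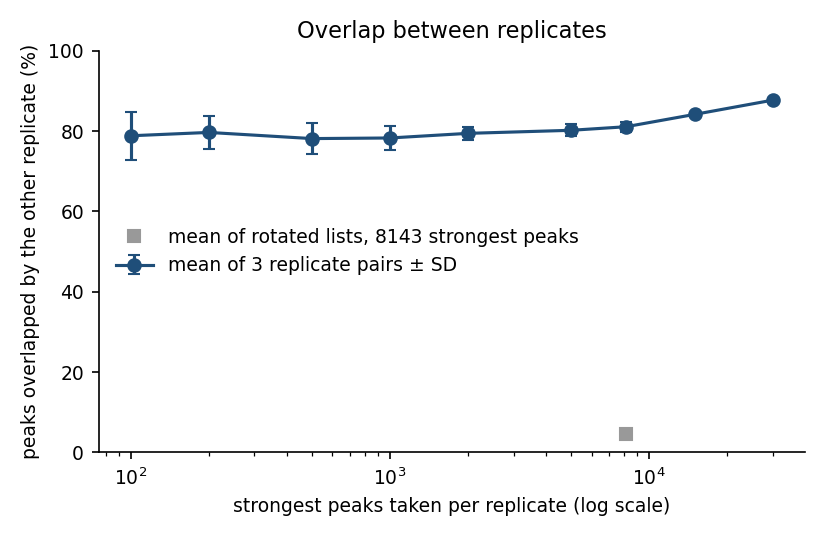
Percent of peaks overlapped by at least 1 bp in the other replicate (vertical axis) against the number of strongest peaks taken from each replicate (log horizontal axis), as mean ± SD of 3 replicate pairs. The share was 78.8% for the 100 strongest peaks and 81.1% for the 8143 strongest, where rotated lists (grey square) gave 4.62%.

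The tagged gene's own locus was examined first among the bound regions. The Bithorax complex, from the 3' end of Ubx to the 5' end of Abd-B (dm6, chromosome 3R, 16656623 to 16972236), held 124 IDR peaks in 316 kb, a density of 393 per Mb and 6.46 times the mean of the arms. The interval between Ubx and abd-A, which contains the bxd regulatory DNA, held 53 peaks at 728 per Mb. The abd-A gene held 15 peaks at 10.8 times the mean, and the interval between abd-A and Abd-B held 36 at 6.09 times. Ubx held 16 peaks (3.38 times) and Abd-B only 4 (1.46 times). Many intervals in the complex, such as 16770534 to 16772548, held several summits, each counted as a peak. This raises these densities, which were not computed by distinct interval. Replicates 1, 2 and 3 placed 126, 126 and 125 of their 8143 strongest peaks in the complex. No other window of this size among 420 along the arms held as many IDR peaks: the next held 75, on 3L from 10730877 to 11046490, and the median window held 19.

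The strongest peak of the genome lay at 3R, 16763081 to 16764749, in an intron of the noncoding RNA gene lncRNA:bxd, 12781 bp from the nearest coding start, that of CG31275. Its signal value was 49.9 ± 5.69 times the list median (SD, n = 3), and it ranked first in each of the 3 replicates. Introns of abd-A held the peaks ranked 3 (3R, 16811485 to 16812451, 24.4 ± 1.37 times the list median, n = 3) and 5 (3R, 16815539 to 16816782, 23.0 ± 1.68 times). A further strong peak covered the abd-A promoter (3R, 16829082 to 16830832, 18.2 ± 2.53 times). The peak ranked 8 (3R, 16799802 to 16802194) lay at the start of a noncoding transcript, and its nearest coding start, that of Glut3, was 12074 bp away. Within Ubx the best peak was intronic (3R, 16702677 to 16703458, 12.8 ± 0.872 times), while the best peak of Abd-B, also intronic, ranked 450 and was absent from the replicate 3 list. How far the tagged transgene extends, how many copies of the locus the line carried and the genotype behind the control library are not given in the sources used here, so density in this region was described and not tested against a copy number.

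**Figure D2:**
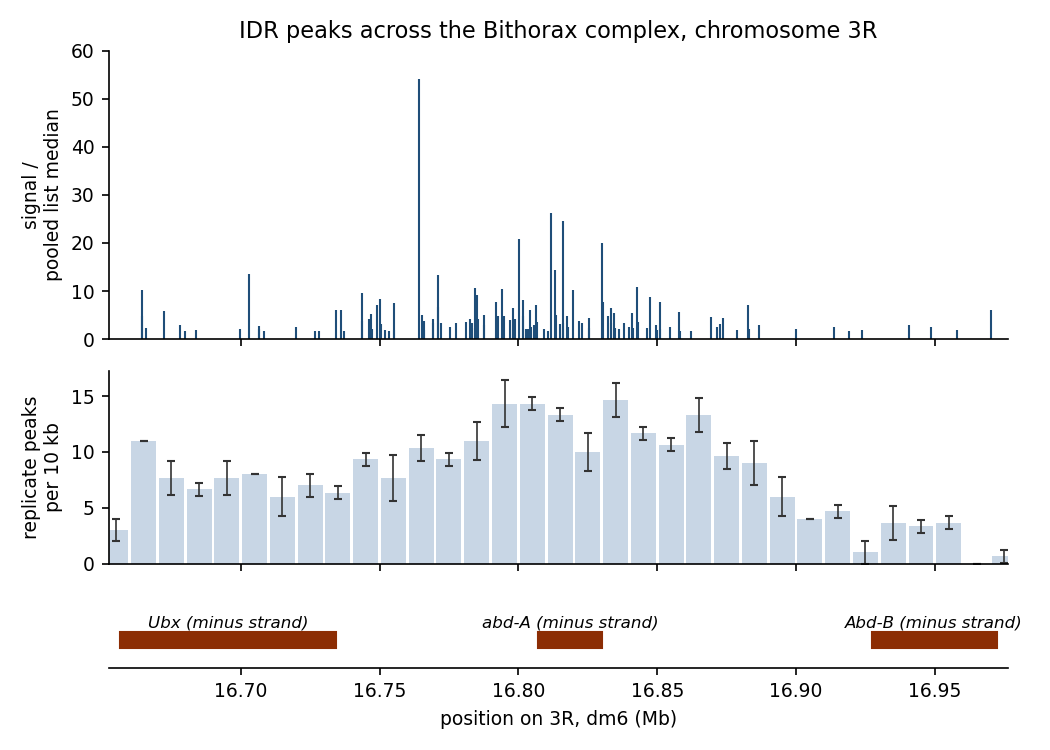
Bithorax complex on chromosome 3R (position in Mb, dm6): IDR peak signal relative to the pooled list median (top), peaks per 10 kb as mean ± SD of the 3 replicates (middle) and the Ubx, abd-A and Abd-B genes (bottom). The tallest line is the lncRNA:bxd intron peak, and few IDR peaks lie in Abd-B.

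Outside the complex the strongest peaks were near genes of several kinds. Around Rh5, a rhodopsin gene of the adult eye, 3 of the 7 strongest peaks fell within 2L, 12002931 to 12012775, all between genes, at 27.3 ± 2.91, 24.4 ± 4.66 and 20.6 ± 2.58 times the list median (SD, n = 3). The promoter of Gapdh2, a glycolytic gene, carried the peak ranked 6 (X, 15867702 to 15868271). Antp, the Hox gene of the thorax, had the peak ranked 9, 1807 bp from its start and over an exon of lncRNA:CR45899 (3R, 7000601 to 7001361, 19.2 ± 0.652 times). The rest of the 20 strongest peaks had their nearest coding starts in tna, CG10543, CG16779, CG43245, CG6191, Sodh1, cbt, RYBP, Dad and gpp, where RYBP encodes a Polycomb-associated protein and gpp the fly's Dot1 histone methyltransferase. Nearness to a start does not show which gene a site acts on, and 9 of these 20 peaks lay over 7 kb from the nearest coding start.

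The next question was which parts of genes were bound. Promoters, within 500 bp of an annotated start, held 27.5% of IDR summits, 2.02 times the 13.6% of rotated positions. Introns held 46.3%, 1.18 times the share of rotated positions, and intergenic DNA 22.7%, or 0.827 times. Summits were nearly absent from coding exons, with 17 summits (0.209%) against 13.1% of rotated positions. 3' UTRs held 0.982% against 4.97%, and exons of noncoding transcripts 1.42% against 0.818%. Each of these 6 shares had a permutation p of 0.00200, the smallest that 1000 rotations can give, and an adjusted p of 0.00233 (two-sided, Benjamini-Hochberg over 7 classes). The share in 5' UTRs did not pass (1.12 times, permutation adjusted p = 0.424). The classes are shares of the same summits, so the near absence from coding exons and 3' UTRs raises the other shares. The promoter and intron folds were not corrected for this. The intron fold of 1.18 therefore does not by itself show a preference for introns.

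Depletion over coding sequence was also present in the replicate lists and extended past the exon edge. Replicate summits numbered 3.08 ± 0.485 per Mb (SD, n = 3) more than 500 bp inside coding sequence and 31.9 ± 1.41 in the first 50 bp outside it. They rose to 203 ± 10.5 per Mb at 200 to 300 bp and 347 ± 1.61 at 1 to 5 kb. Of all 30000 pooled summits, 0.740% lay in coding sequence, which makes up 17.1% of the arms. Set against the 21857 weaker pooled peaks, a background added after the data were seen, the promoter share of IDR peaks was still 1.83 times higher (Fisher's exact test, adjusted p = 1.66e-127), but the intron share turned to 0.844 times. Against these peaks the coding-exon share was 0.419 times (Fisher's exact test, adjusted p = 0.000678), a smaller depletion than against rotated positions, and the 3' UTR share was 1.07 times (0.589).

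**Figure D3:**
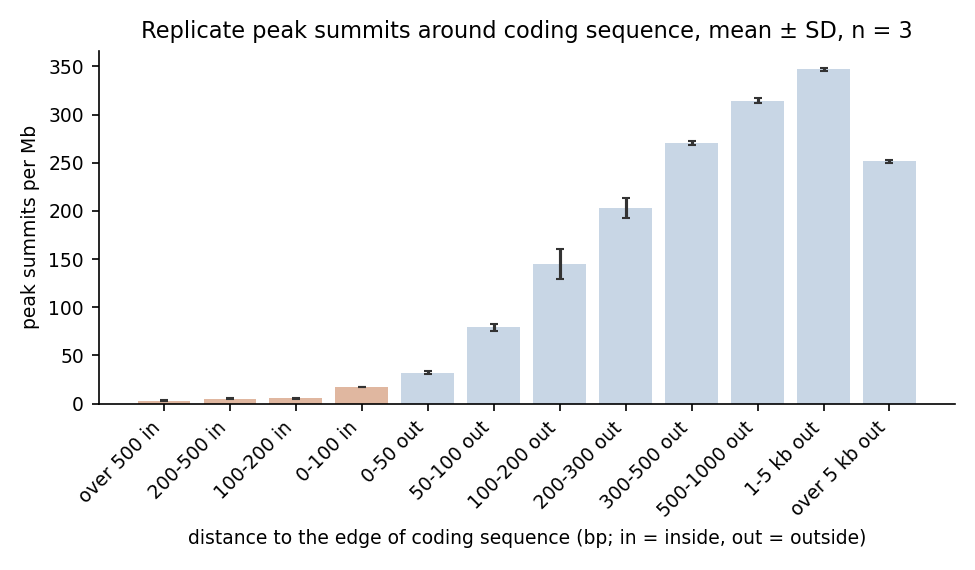
Peak summits per Mb (vertical axis, mean ± SD of the 3 replicate lists) by distance to the nearest edge of coding sequence in bp, inside (orange) or outside (blue). Density was 3.08 per Mb deep inside coding sequence and 347 per Mb at 1 to 5 kb from it.

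Chromosome arms differed in peak density. The autosomal arms 2L, 2R, 3L and 3R carried 66.9, 62.8, 63.1 and 63.9 IDR peaks per Mb. The X carried 48.5 per Mb, or 14.0% of peaks (95% Clopper-Pearson interval 13.3 to 14.8) on 17.6% of the length. Chromosome 4, which is largely heterochromatic, carried 17 peaks, 12.6 per Mb and 0.207 times the mean of the arms. Among all pooled peaks the X stood at 0.983 times the mean and chromosome 4 at 0.0927 times. The embryos were of both sexes, so the X was present at a lower average copy number than the autosomes.

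Developmental genes were then compared with genes of the same length. In total 3694 protein-coding genes (26.5%) had an IDR summit in the gene body or within 2 kb of it. The Hox cofactor list held cofactors or collaborators of Hox proteins. It shared 3 genes with the segmentation list, so the results of these lists are not independent. Hox cofactors were bound more often than length-matched genes, 8 of 9 against 3.62 expected (permutation adjusted p = 0.0133). Peaks numbered 24 at hth, the Hox-partner homeodomain gene, 6 at tsh and 3 at its paralogue tio. Heart genes were bound in 12 of 14 cases against 6.40 (permutation adjusted p = 0.0133), led by lbe, mid and tup, regulators of heart and muscle cells. Segmentation genes were bound in 15 of 24 cases against 8.23 (permutation adjusted p = 0.0133), with 11 peaks at the Wnt antagonist nkd, 9 at inv and 6 at ptc, the Hedgehog receptor. Signalling genes were bound in 30 of 37 cases against 21.6 (permutation adjusted p = 0.0133), with 21 peaks at fz2 and 18 at fz, both Wnt receptor genes. These p-values are two-sided, from 10000 random lists matched on gene length, adjusted over 21 lists. When genes were matched instead on sequence over 300 bp from coding exons, a choice made after the data were seen, the calls ended for Hox cofactors (1.73 times, permutation adjusted p = 0.0966), segmentation genes (1.27 times, 0.442) and signalling genes (1.27 times, 0.0560). Heart genes stayed past the threshold under that matching (1.65 times, permutation adjusted p = 0.0428) but not without replicate 1 (1.62 times, 0.125) or in the stronger 50% of IDR peaks (1.52 times, 0.567), where segmentation genes did not pass either (1.72 times, 0.175). Signalling genes did not pass with starts within 1 kb in place of the gene window (1.39 times, permutation adjusted p = 0.125), and with a 10 kb window none of the 4 lists passed (1.25 to 1.47 times, 0.0980 to 0.253).

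The Hox genes as a list were not bound more often than genes of their length, 5 of 8 against 5.97 (permutation adjusted p = 0.731). This fold of 0.838 turned to 1.07 in the stronger 50% of IDR peaks. Against lists not matched on length it was 2.34 times (permutation adjusted p = 0.0979). The Hox genes had a median of 2.5 peaks per gene against 2.28 in length-matched lists (percentile 61.1). Peaks were at trunk members: 20 at abd-A, 18 at Ubx and 22 at Antp, counting 2 kb on each side, then 4 at Abd-B and 1 at the Scr promoter. The head genes lab, pb and Dfd had none. Textbook targets of abd-A or Ubx were bound in 14 of 16 cases against 10.2, which did not pass (1.37 times, permutation adjusted p = 0.0928), although it did without replicate 2 (adjusted p = 0.0388), without replicate 3 (0.0315) or against lists not matched on length (3.33 times, 0.000700). In the stronger 50% of IDR peaks 8 of these 16 genes were bound, 1.01 times the expected number (permutation adjusted p = 1.00), and matching on sequence far from coding exons gave 1.25 times (0.363). Beyond Antp and Ubx, the most peaks in this list were at grh (9, the best in an intron at 2R, 17804559 to 17805431), Con (4) and opa (3). The midgut signal genes dpp and wg each had their best peak at a promoter (2L, 2427923 to 2428334 and 2L, 7306869 to 7307068), at 3.19 ± 0.356 and 2.84 ± 0.269 times the list median (SD, n = 3). The cell death gene rpr had its best peak upstream of the gene, between genes (5.13 ± 0.0898 times), and salm its best between genes (7.16 ± 0.982 times). Single peaks or pairs were at rho, svp, Ih, Ndae1 and betaTub60D. The limb gene Dll and the LIM-homeodomain gene ap, both described as repressed or regulated by abdominal Hox proteins, had no IDR peak within 2 kb. With the gene body extended by 10 kb, 15 of the 16 genes were bound, so Dll or ap had a peak in that wider window.

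Tissue lists gave no further call by genes bound when matched on length. By median peaks per gene, visceral mesoderm and midgut genes had 3 against 1.06 in random lists (percentile 98.7). The lists of cofactor, heart, segmentation and signalling genes stood at percentiles 93.6 to 99.2 on that measure. The other tissue lists stood at 32.2 to 89.6. Mesoderm and muscle regulators were bound in 14 of 21 cases (permutation adjusted p = 0.166), with 10 peaks at the muscle factor Mef2, 5 at zfh1 and 4 at lbe. Visceral mesoderm and midgut genes were bound in 11 of 14 cases (0.180), among them pnt, tsh and jeb, and oenocyte genes in 6 of 7 (0.180), among them spi, Hnf4 and salm. Neuron and glia genes were bound in 12 of 16 cases (0.630), with 14 peaks at the potassium channel gene Sh and 8 each at ChAT and brp, and neuroblast genes in 8 of 19 (0.813), led by grh, Dr and SoxN. Trachea and epidermis genes were bound in 9 of 16 cases (1.00), led by grh, bnl and knrl. Hemocyte genes, markers of blood cells, were bound in 2 of 13 cases against 5.95 expected (0.0560), namely ush with 21 peaks and gcm2 with 2. Germline genes were bound in 2 of 10 cases (0.731), namely vas and osk. The only peak counted for osk lay past its 3' end, over the neighbouring gene ScsbetaA. The values in brackets are permutation p-values adjusted over the 21 lists, and a list that misses the threshold is not shown to be bound like other genes. Against lists not matched on length, mesoderm, visceral, neuron and glia, oenocyte and trachea genes passed. Their folds were 2.52, 2.97, 2.82, 3.25 and 2.12 times, with permutation adjusted p from 0.000933 to 0.0384. Neuroblast, hemocyte and germline genes did not pass there either.

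Constitutive and adult gene lists served as other backgrounds. The tRNA list was fixed beforehand because such units are often seen as nonspecific ChIP signal, which was not tested here. Ribosomal protein genes, chosen by symbol, were bound more often than length-matched genes, 25 of 92 against 14.7 (1.70 times, permutation adjusted p = 0.0210), with 4 peaks at RpS13 and 3 each at RpLP0-like and RpS21. The best peak counted for RpLP0-like lay over the neighbouring gene 14-3-3zeta. tRNA genes were bound in 109 of 290 cases against 88.6 (1.23 times, permutation adjusted p = 0.0133), with 4 peaks shared by the neighbouring tRNA:Glu-TTC-1-4, tRNA:Glu-TTC-1-5 and tRNA:Glu-TTC-1-6. The number expected for tRNA genes was 57.2 without replicate 1 and 77.6 without replicate 2. Their random lists could repeat genes where few other noncoding genes matched in length, so this call is uncertain. Odorant, gustatory and ionotropic receptor genes were bound less often, 19 of 179 against 32.7 (0.581 times, permutation adjusted p = 0.0138), with 2 peaks each near Gr47b, Or45b and Ir85a. No peak lay near the 111 histone genes (17.6 expected, permutation adjusted p = 0.00420), which are near-identical copies in a cluster where reads may not be placed. Proteasome genes (6 of 48, with Rpn13, Prosalpha3 and Prosbeta5R2), seminal fluid genes (9 of 47, with Sfp65A, Acp26Ab and Acp26Aa) and chorion genes (0 of 14) did not pass (permutation adjusted p = 0.731, 0.709 and 0.238). Against lists not matched on length, proteasome (0.471 times, permutation adjusted p = 0.0456) and chorion genes (0.0402) were called as bound less often. Seminal fluid genes then went from 1.27 to 0.723 times, without a call (0.386). The receptor call ended without any of replicates 1, 2 or 3 (0.651, 0.662 and 0.679 times, permutation adjusted p = 0.125, 0.103 and 0.132), in the stronger 50% of peaks (0.535 times, 0.0700) and with a 10 kb window (0.883 times, 0.253). It stood with starts within 1 kb (0.299 times, permutation adjusted p = 0.00336) and against lists not matched on length (0.397 times, 0.000700). The ribosomal call ended with that window (1.17 times, permutation adjusted p = 0.253), without replicate 1 (1.70 times, 0.0931) and against lists not matched on length (1.03 times, 0.972), and the tRNA call with starts within 1 kb in place of the gene window (1.19 times, 0.101). Neighbouring tRNA genes share peaks and the histone genes lie together, so members are not independent and their p-values are too small.

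**Figure D4:**
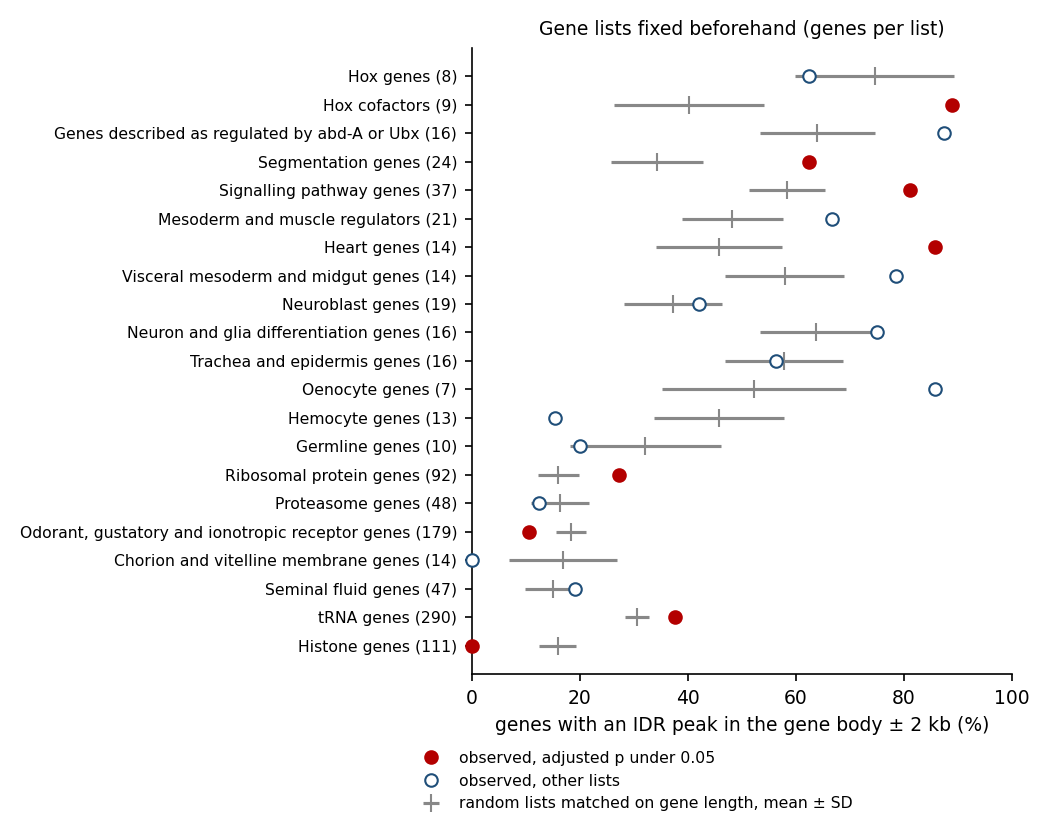
Percent of genes in each of 21 lists with an IDR summit in the gene body or within 2 kb (circles, filled where the adjusted p is under 0.05) beside the mean ± SD of random lists matched on gene length (grey). Hox cofactors lie farthest above their random lists, at 88.9% against 40.2%, and no histone gene was bound.

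Of all coding genes, sbb carried the most IDR peaks, 35, and pum, an RNA-binding translational repressor, carried 33. MSAmiP, between abd-A and Abd-B, carried 32, the best being the peak at the abd-A promoter, and the overlapping genes CG46467 and Glut4EF shared 31. jing, Eip75B, an ecdysone-induced nuclear receptor gene, and kirre, a myoblast fusion gene, carried 26 each, and Tlk and tara 24 each. Long genes collect more peaks, and these counts were not adjusted for length.

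Sequence words at the summits were compared with the flank of the same peak. Words carry the name of the factor assigned to them beforehand, and whether that factor or abd-A contacts them was not tested. TTTATGG was fixed as a posterior Hox word. It lay within 50 bp of 5.70% of summits and in 3.12% of windows 500 bp away (1.83 times, exact adjusted p = 5.77e-15). The GAGA factor (Trl) word GAGAGAG was present at 4.27% against 1.72% (2.49 times, exact adjusted p = 5.29e-21), and the DRE word TATCGATA at 0.479% against 0.246% (1.95 times, adjusted p = 0.0293). The general homeodomain words were rarer at summits than 500 bp away: TTAATTA at 3.35% against 5.22% (exact adjusted p = 2.85e-08), TTTATTA at 5.73% against 7.05% (adjusted p = 0.00155) and the Exd-Hox word TGATTWAT at 1.45% against 2.22% (adjusted p = 0.000672). Compared with 51 bp windows 100 bp to the left and right, a comparison chosen after the profile was seen, TTTATTA was more frequent at the summit (1.70 times, exact McNemar test, adjusted p = 1.45e-06 on both sides), as was TTAATTA (1.40 times, 0.00176 and 0.0450). Those windows lay at the lowest points of the profile on each side for both words, so these p-values restate a dip already seen. In the stronger 50% of peaks the calls ended for TTTATTA (0.860 times, exact adjusted p = 0.116) and TGATTWAT (0.700 times, 0.0712), and the TATCGATA call ended without replicate 1 (1.86 times, 0.129). Words of GATA factors (WGATAAR, 0.716 times), Twist (CATATG, 0.778 times), Tinman (CACTTGA, 0.732 times) and Su(H) (TGGGAA, 0.801 times) were also rarer, with adjusted p of 1.74e-08, 0.00840, 0.0210 and 0.000672. No call was made for TTAATGA, TGATTTAC, TGACAG (Hth), CAGGTAG (Zelda), AACYGGTT (Grh) or GGTCACACT (Motif 1), with adjusted p from 0.0510 to 0.784. AACYGGTT and GGTCACACT were called as enriched with 100 bp on each side (1.5 and 2.09 times, exact adjusted p = 0.00109 and 0.00542) and with flanks at 1000 bp (1.63 and 2.88 times, 0.0142 and 0.0244). TTAATGA was called as depleted with 100 bp on each side (0.804 times, exact adjusted p = 0.00174) and CAGGTAG with flanks at 1000 bp (0.563 times, 0.0361). These are exact McNemar tests over 8143 peaks, two-sided and adjusted over 16 words. Summits held 44.9% G and C against 39.0% in flanks, which moves with the lower share of words made of A and T, and against flanks 1000 bp away TTTATTA turned to 1.12 times (exact adjusted p = 0.128). With those flanks the calls also ended for the GATA word (0.885 times, exact adjusted p = 0.0665), the Twist word (0.898 times, 0.309) and the Su(H) word (0.892 times, 0.101), and the Su(H) call ended with 100 bp on each side (0.945 times, 0.223).

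**Figure D5:**
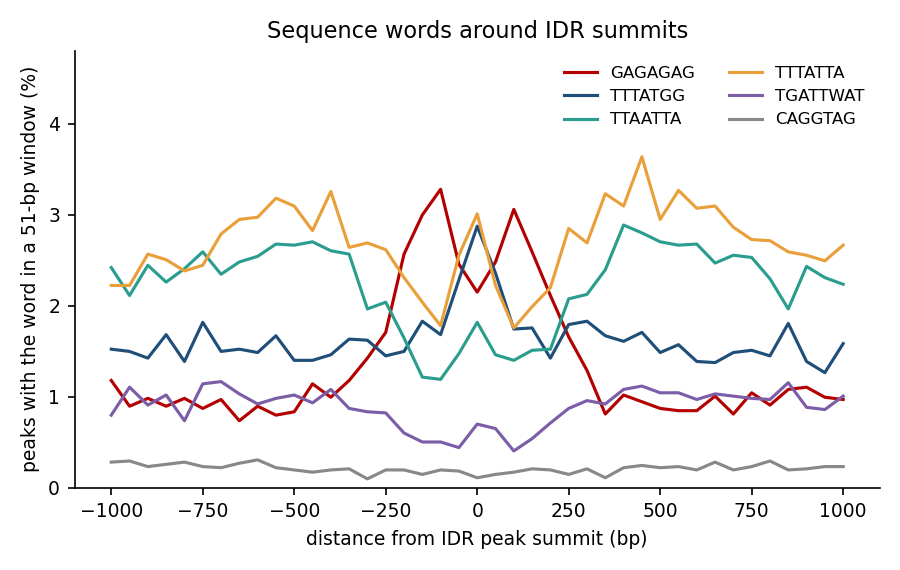
Percent of IDR peaks with each word, on either strand, in windows of 51 bp (vertical axis) by distance from the summit in bp. TTTATGG reached 2.87% at the summit, and GAGAGAG had 2.15% at the summit and 3.28% at 100 bp to its left.

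Stronger peaks were more often at promoters. In the strongest 20% of the IDR list, 30.7% of 1628 summits lay in promoters, against 23.1% of the weakest 20% (Fisher's exact test, two-sided, adjusted p = 4.12e-06 over 3 features). The Hox words TTAATTA or TTAATGA were present at 6.02% and 4.91% of these summits (exact test, adjusted p = 0.190). GAGAGAG was present at 5.41% and 3.62% (1.49 times, exact adjusted p = 0.0268), but this call ended when replicate 1, 2 or 3 was left out (1.20, 0.986 and 1.24 times, with exact adjusted p = 0.527, 1.00 and 0.396).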

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

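Alternatives numbered 380 over 59 results. Of these, 308 were counted as the same (side of the threshold kept, or a move within the spread), 29 lost the call, 16 gained one, 23 moved and 4 reversed. Results without a call also turned direction in places, as the Hox gene list did from 0.838 to 2.34 times without length matching. The weaker pooled peaks as background, all pooled peaks for chromosome densities and matching on sequence far from coding exons were chosen after seeing the data. The overlap between replicates, 81.1%, was 64.9% when 50% of both peaks had to overlap, 70.9% for summits within 100 bp and 78.3% for the 1000 strongest peaks, and ran from 80.3% to 82.5% with 1 replicate left out. Support of IDR peaks per replicate, 88.4%, was 66.4% and 82.3% under those 2 overlap rules. Stricter rules count fewer peaks as shared by construction. Promoter enrichment and coding-exon depletion kept direction and call under each alternative run, but against weaker pooled peaks the coding-exon fold moved from 0.0160 to 0.419. With that background the intron fold reversed to 0.844 and the 3' UTR fold to 1.07. The 6 lists bound more often became 4 without replicate 1, 7 without replicate 2 or 3, 4 with starts within 1 kb, 4 in the stronger 50% of peaks, 1 with a 10 kb window, 11 without length matching and 3 (heart, ribosomal protein and tRNA genes) when matched on sequence far from coding exons, and the heart and segmentation calls ended in the stronger 50% of peaks (1.52 and 1.72). The 2 lists bound less often became 1 with a 10 kb window, 4 without length matching and 1 in the stronger 50% of peaks, and numbered 1 to 1 with 1 replicate left out. A 10 kb window reaches neighbouring genes, and the stronger 50% and the lists with 1 replicate left out have fewer peaks. Other causes were not tested. The 3 words enriched at summits became 5 with 100 bp on each side and 5 with flanks at 1000 bp, gaining AACYGGTT and GGTCACACT in both; with the latter flanks 4 words were depleted in place of 7 (TTAATTA, TGATTWAT and CACTTGA of those 7, and CAGGTAG at 0.563, not called before) and TTTATTA reversed to 1.12; the cause was not tested. GAGAGAG in strong over weak peaks, 1.49, ran from 0.986 (reversed, without replicate 2) to 1.24 with 1 replicate left out; the cause was not tested. Density of the X, 0.797 of the mean, was 0.675 in the stronger 50% of peaks and 0.983 among all pooled peaks, and that of chromosome 4, 0.207, was 0.0927 among all pooled peaks. Depth could not be assessed from peak lists, so a region without a peak is not shown to be unbound. No paired analysis was possible because the series has 1 group.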

Other observations

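All tests in this part except that of GC content in coding exons were chosen after the related results had been seen. Further gene groups were compared with genes of the same length. Polycomb and trithorax group genes were bound in 18 of 35 cases against 16.1 for genes of the same length (1.12 times, permutation adjusted p = 0.601). Ecdysone response genes were bound in 14 of 17 cases against 12.3 (1.14 times, permutation adjusted p = 0.601). Without the genes already named, the counts were 15 of 30 and 13 of 16 (permutation test, both adjusted p = 0.601), and a p that misses the threshold does not show that these genes are bound like others.

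Among 7929 words of 7 bases, 1331 were more frequent at IDR summits than 500 bp away and 1133 were less frequent (binomial test on counts, adjusted). This test ignored the pairing of summit and flank and did not adjust for base composition. Summits held 44.9% G and C against 39.0% in flanks, so many of these words can differ for that reason. CACACAC was first, at 9.11% of summits against 4.36%. CTCGCTC, whose other strand reads GAGCGAG, followed at 3.93% against 1.11% (3.56 times). The GAGA factor word GAGAGAG was at place 11 and the posterior Hox word TTTATGG at place 35. GCCATAA, whose other strand TTATGGC overlaps TTTATGG, was at place 25 (2.19 times). Which protein these overlapping words reflect was not tested.

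Coding sequence held 0.0329 of the pooled summit density found over 1 kb from it. The tables argue against GC content: relative to windows of the same GC content the ratio was 0.0205 ± 0.00129 (SD, n = 3). Transcription of the gene, or its transcripts among the reads, is argued against for receptor, chorion and seminal fluid genes, taken as silent in embryos without an expression measurement, whose coding exons together held 3, 0 and 1 summits in replicates 1, 2 and 3, against 86.3 expected per replicate (ratio 0.0155 ± 0.0178). For noncoding exons over 500 bp from coding sequence, spliced transcripts among control or ChIP reads stay open, because all such exons together had 1.09 ± 0.0220 times the density of other sequence but 3' UTRs alone had 0.236 ± 0.0103. The control library was not analysed here, so an excess of exon reads in it remains a candidate cause for the 222 pooled summits being so few, and no biological explanation was tested.

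Peaks in the Bithorax complex were dense and strong. Extra copies of the locus, if the tagged transgene added any, could raise both. The sample source names an insertion targeting abd-A, which does not say whether a copy was added. The median pooled signal in the complex was 1.48 times the list median, and 1.53 ± 0.0595 times over the replicate lists (SD, n = 3). This lay above the central 95% of 356 windows of the same size (0.771 to 1.42) and below the highest (2.07). Extra copies and binding cannot be told apart here, since the transgene's extent, the copy number and the genotype of the control are not given in the sources used here.

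Base composition was weighed for the Hox words at summits, and contact of any protein with these words was not tested. For TTAATTA and TTTATTA the ratios of 0.642 and 0.814 to flanks lay within those of words made of the same bases (5th to 95th percentile 0.478 to 0.844 and 0.538 to 0.863), so their lower frequency is consistent with base composition. TTTATGG, at 1.83, ranked first of 105 words of its bases (0.652 to 1.25), which composition alone does not give. Within 100 bp, TTTATTA was 1.70 times as frequent in the 51 bp at the summit as 100 bp to either side (exact McNemar test, adjusted p = 1.45e-06 on both sides), above the range of words of its bases (1.10 to 1.57), whereas TTAATTA, at 1.40, and TTAATGA, at 1.33, lay within theirs (1.02 to 1.46 and 0.803 to 1.60). For TTTATTA the windows 100 bp away (1.78% and 1.76%) were the lowest of its profile, so its p-values restate a dip already seen. The words of its bases had no distance picked for them. Its place above their range therefore does not decide about base composition. TTTATGG, at 1.68, lay above its range (0.752 to 1.39), and GAGAGAG was less frequent at the summit than 100 bp to either side (0.678 times, exact McNemar test, adjusted p = 1.66e-05 and 0.000538), within its range (0.639 to 1.11). Against flanks 500 bp away, however, GAGAGAG at 2.49 times lay above the range of words of its bases (0.981 to 2.06).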
